A study of Mus musculus with 6 samples.

How the data were processed

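The arrays measured total RNA, extracted from fresh tissue and labelled with biotin per the labels' protocols, from 3 samples of mouse pancreatic ductal adenocarcinoma (PDAC) and 3 samples of control pancreas. The probe table's header names the platform as Affymetrix Mouse Gene 1.0 ST, an array whose probe sets draw on probes spread along each gene. The deposited values are log2 expression values per probe set, and the submitters' processing notes name the affy package and RMA, a procedure that corrects background, normalizes between arrays and summarises the probes of a probe set. Versions are not given in the sources used here. The values ran from 2.28 to 14.42, and the array medians lay between 6.65 and 6.78. No value was missing. Scanner files and detection calls are not used here, so no probe set could be called absent, and changes of dim probe sets are understated by the background signal. Very bright probe sets lie where an array responds weakly to more RNA, so their changes can be understated too.

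Of the 34760 probe sets, 21640 carried 1 gene symbol in the annotation table, 1321 carried several and 11799 were not named there. The annotation table is dated. Its Entrez identifiers matched the reference gene table (RefSeq) for 21553 probe sets, and 0 symbols changed by that match. Probe sets with several symbols were left out of the gene comparison. For each of the 19937 genes, the probe set with the highest mean over the 6 arrays was used, since 954 genes had 2 or more. Among those genes, 37 had probe sets past the threshold in opposite directions. Probe sets can cross-hybridise between close relatives, so values of kallikreins, trypsins, amylases, elastases, mast cell proteases, immunoglobulins and ribosomal proteins are uncertain as to the family member. No genome build is given in the sources used here, and no coordinates are printed.

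Groups came from the sample titles. The comparison of PDAC with control pancreas used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, all 6 arrays), with Benjamini-Hochberg adjustment over the 19937 genes. The threshold was an adjusted p under 0.05, and the count that also changed by at least 1 on the log2 scale (2-fold) was kept beside it. Standard errors and intervals at the 95% level come from the same fit, and group means are given with their SD over 3 arrays. The 35 gene lists, their tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 768 list entries, 692 had a value. The 34 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and 3 genes stood in more than 1 list.

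Genes were named by this rule: the 12 largest rises and the 12 largest falls among genes past the threshold whose PDAC values all lay on the same side of all control values; in each list, up to 4 members with the largest change in the commoner direction and up to 2 in the other, or 2 where none passed; and always Cdkn2a, Pdx1, Smad4, Xist and the first member of each list. Kras, Trp53, Ldlr, Ddx3y, Ins1, Cd19, Plp1, Hba-a1, Cdkn1a and Rpl3, which the rule also names, are not analysed here. The rule let the text leave out genes named for a list or always. Genes named outside the rule are said to be so, singly or for a whole part of the text.

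The fit was tested on simulated data made from the control means and residual spreads of the same 19937 genes, with 200 genes changed. For the comparison of PDAC with control pancreas it recovered 8.82% of genes changed by 0.5 on the log2 scale, 77.8% of those changed by 1 and 88.3% of those changed by 2, with 7 false calls, 5.74% of all calls. Only these 200 genes were changed, while 59.13% of genes passed in the data, and the adjustment is stricter where fewer genes change. The recovery rates thus do not describe the comparison of the data themselves. In the same simulated comparison over 19937 genes the set test called 5 of 5 raised lists and 0 of 30 unchanged lists. The simulated genes varied independently, so that test says nothing about lists whose members vary together.

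Alternatives were a filter that left out the dimmer probe sets, scaling each array on the median of the ribosomal protein list, a second quantile normalization, the mean of a gene's probe sets, a variance trend with robust shrinkage, array weights, the replicate number as a block, age as a covariate, no variance shrinkage, an adjusted p under 0.01, leaving out each array, an estimated correlation in camera, and fry in place of camera. Scaling each array to 1 common median over all genes was added after seeing the data, because the deposited array medians differed. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 joined the tables and drew the figures.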

Results

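Gene expression was measured on 1 array per sample in 3 advanced tumours and 3 control pancreases of male mice of a mixed genetic background. The tumours arose where Cre recombinase, driven by the Pdx1 promoter of pancreatic progenitors, deleted both copies of the Ink4a/Arf tumour suppressor locus and switched on an oncogenic Kras allele. Controls carried the same floxed alleles without Cre. The tumours were taken at 10, 8.5 and 7 weeks of age (PDAC replicates 1, 2 and 3) and the controls at 9 weeks. The values are log2 expression values normalized by the authors. Pearson's correlation over all 34760 probe sets was 0.983 to 0.9838 between control arrays, 0.9814 to 0.9842 between PDAC arrays and 0.8858 to 0.9082 between arrays of different groups. The median SD of a gene was 0.133 in control pancreas and 0.139 in PDAC. The 3 tumours carry different ages, but nothing in the labels says that the control samples came from separate mice, so p-values measure the spread between these samples. The number of arrays limits the precision, and any processing batch is not given and cannot be told apart from group.

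The comparison asked which genes differ between advanced PDAC and normal pancreas. Genes of tissue remodelling and of gastric-type epithelium and 2 mast cell protease genes were among the largest rises, and genes of the digestive secretory cells (acinar cells) were among the largest falls. The largest measured rise was that of Mcpt2, a mast cell chymase, from 4.23 ± 0.09 in control pancreas to 10.97 ± 0.42 in PDAC (SD, n = 3 each). Its control value lies below the median of olfactory receptor genes there (4.45), so background limits the size of this change. Mcpt1, a relative of Mcpt2, rose by 6.01 ± 0.35 (log2 change ± SE, as below). Ctse (cathepsin E, an aspartic protease of gastric epithelium) rose by 6.52 ± 0.11, the matrix protein gene Tnc by 6.48 ± 0.16 and the metalloprotease inhibitor gene Timp1 by 6.06 ± 0.16. Gkn2, Col12a1, Lcn2, Cdh17, Itga2, Gabrp and Mmp7 rose by between 4.92 and 5.41. Pdia2, a pancreatic disulfide isomerase, fell by 6.58 ± 0.83, Serpini2 by 6.48 ± 1.10, Klk1b5 by 6.45 ± 0.66, the trypsin inhibitor gene Spink1 by 6.35 ± 0.96 and the chymotrypsin gene Ctrc by 6.27 ± 0.60. Tmed6, Cela1, Pla2g1b, Cuzd1, Tmed11 and Aqp12 fell by between 5.55 and 5.89. The amino acid transporter gene Slc38a5 fell by 5.72 ± 0.11, from 11.84 ± 0.16 to 6.12 ± 0.04. Adjusted p lay between 5.98e-07 and 0.00197 for these 24 genes (limma with Benjamini-Hochberg adjustment), and all 3 PDAC values lay beyond all 3 control values.

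**Figure D1:**
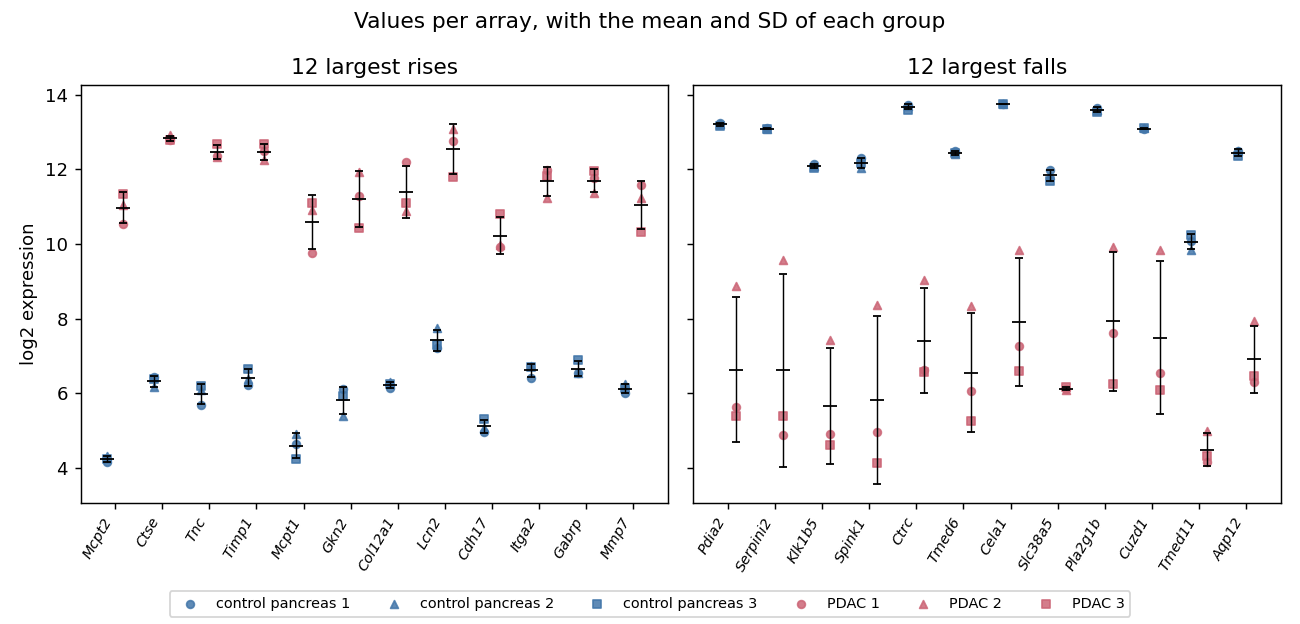
Log2 expression per array (points, marked by replicate) of the 12 genes with the largest rises and the 12 with the largest falls, with the mean and SD of each group (black). Control values of the falling genes lie close together, while PDAC replicate 2 (triangles) lies highest of the 3 tumours for most of them, as for Serpini2, whose PDAC values have an SD of 2.58.

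In all, 11789 of 19937 genes (59.13%) passed the threshold, 5408 of them higher and 6381 lower in PDAC. At least 2-fold changes were found for 2348 higher and 1177 lower genes, and changes of 3 or more on the log2 scale for 220 higher and 112 lower genes. Groups did not overlap for 68.82% of genes, where chance gives 10%. The median change of all genes was -0.12. Under a scaling on ribosomal protein genes it became 0.57 and the counts turned to 13117 higher and 994 lower, so the balance of rises and falls rests on the normalization. Under the deposited scaling and all 3 others tried, 4166 genes were higher and 994 lower, and 1883 and 424 of them by at least 2-fold in each.

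Cdkn2a, the gene of the Ink4a/Arf locus that the tumour genotype deletes, had a value of 6.96 ± 0.13 in control pancreas and 6.95 ± 0.14 in PDAC, a log2 change of -0.01 with a 95% interval of -0.28 to 0.26 (adjusted p = 0.95). It has 1 probe set, whose place relative to the deleted exons is not known here, so this value does not check the deletion. Under the ribosomal scaling its change was 0.68 and passed (adjusted p = 0.00261). Pdx1 fell by 0.46 ± 0.15 (adjusted p = 0.0354). That call was lost without control replicates 2 (-0.50) or 3 (-0.35), without PDAC replicates 1 (-0.35) or 2 (-0.44) and without variance shrinkage, and its sign turned under the ribosomal scaling (0.23). Smad4 rose by 0.44 ± 0.10 (adjusted p = 0.00729). Xist, which female cells express, was 4.89 ± 0.17 in control pancreas and 4.62 ± 0.16 in PDAC, all labelled male (adjusted p = 0.105). It passed as a fall with median scaling (-0.45) and as a rise under the ribosomal scaling (0.42).

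Nearly all acinar genes fell. Of 27 measured genes of digestive enzymes and granule proteins, 26 fell and 0 rose, with a median log2 change of -4.21, and Dnase1, named after its values were seen, did not pass (-0.23, adjusted p = 0.101) but fell with median scaling (-0.41) and rose under the ribosomal scaling (0.46). The first list member Amy1, an amylase gene, fell by 4.97 ± 0.63. In control pancreas, 20 of the 27 had a mean within 1 log2 of the highest value of the table. PDAC replicate 2 stood apart, with a list median of -1.79 against the control means where PDAC replicates 1 and 3 had -5.23 and -5.54, and without it the list's median change was -5.22. Of 12 acinar transcription factor genes, 11 fell and 1 rose (median -1.85; 8 and 2 under the ribosomal scaling). Bhlha15 (Mist1, a factor of secretory maturity) fell by 5.40 ± 0.49, Ptf1a by 4.60 ± 0.23, Rbpjl by 4.0 ± 0.5 and Nr5a2 by 3.14 ± 0.46. Creb3l2 rose by 0.65 ± 0.17, a call lost without control replicate 1 (0.59), without variance shrinkage and with median scaling. Among 31 genes of protein folding and translocation in the endoplasmic reticulum, 22 fell (23 adjusted over the list alone) and 5 rose (median -0.82), against 14 and 9 with a median of -0.13 under the ribosomal scaling. Ero1b, an oxidase that forms disulfide bonds, fell by 4.50 ± 0.19, Edem2 by 2.67 ± 0.14 and Herpud1 by 2.17 ± 0.16, while the disulfide isomerase gene Pdia3 rose by 0.72 ± 0.13. The chaperone gene Hspa5 fell by 0.41, a call lost in the fits without control replicates 1 (-0.32) or 3 (-0.43) and without PDAC replicates 1 (-0.33) or 2 (-0.39), with the second quantile normalization, the replicate block and no variance shrinkage, and above 0 under the ribosomal scaling (0.28). Among 22 genes of amino acid synthesis and transport, 16 fell and 2 rose (median -1.38; 12 and 6 with -0.69 under the ribosomal scaling). Gnmt, which methylates glycine, fell by 4.47 ± 0.27, the transsulfuration genes Cth and Cbs by 3.57 ± 0.16 and 3.36 ± 0.25, Gamt of creatine synthesis by 3.04 ± 0.12 and Phgdh of serine synthesis by 2.43 ± 0.15. Bcat1 rose by 1.76 ± 0.21 and Glul by 0.91, the latter call lost without PDAC replicate 1 (0.81) and without variance shrinkage. Camera with Benjamini-Hochberg adjustment over the lists gave these 4 lists an adjusted p of 4.57e-06, 0.000299, 4.08e-05 and 4.08e-05, in that order, and with an estimated correlation the adjusted p was 0.495, 0.324, 0.241 and 0.241.

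**Figure D2:**
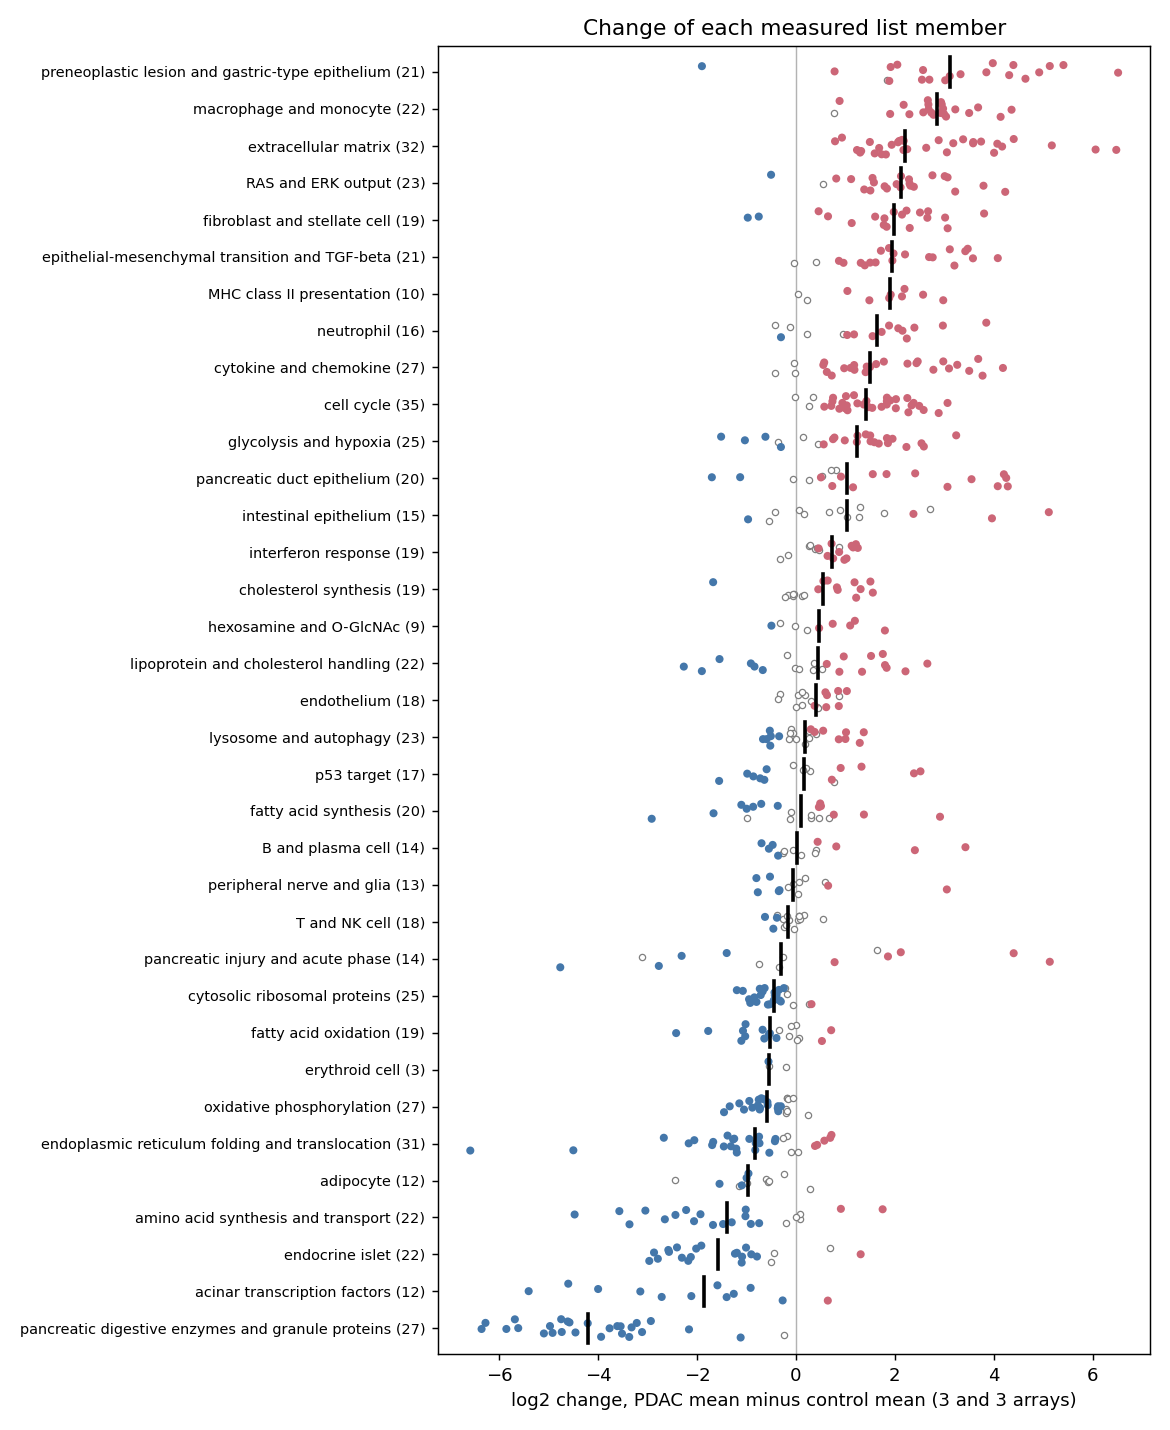
Log2 change (PDAC mean minus control mean, horizontal axis) of each measured member of the 35 gene lists (vertical axis, number measured in brackets); filled points passed the threshold (red higher, blue lower), open points did not, and black bars are list medians. Medians run from -4.21 for digestive enzymes to 3.11 for gastric-type epithelium. Under the ribosomal scaling those of the oxidative phosphorylation and fatty acid oxidation lists turn to 0.12 and 0.17, below the median of all genes there (0.57). That of the ribosomal protein list is 0.24 there, near 0 by construction.

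Genes of preneoplastic and gastric-type epithelium rose as a list, with 19 of 21 higher (20 adjusted over the list alone) and a median of 3.11. Beside Ctse, Gkn2, Lcn2 and Mmp7, the gastric mucin gene Muc5ac rose by 2.70 ± 0.35. Tff2, a trefoil peptide gene of mucous cells, fell by 1.90 ± 0.28 from a control value of 13.65 ± 0.01. Of 20 duct genes, 13 rose (15 adjusted over the list alone) and 2 fell (median 1.04). The keratin gene Krt7 rose by 4.29 ± 0.22, the carbonic anhydrase gene Car2 by 4.25 ± 0.14, the chloride channel gene Cftr by 4.21 ± 0.13 and Krt19 by 2.41 ± 0.20. Onecut1, a factor of duct development, fell by 1.70 ± 0.21 and the mucin gene Muc1 by 1.13 ± 0.14, a call lost under the ribosomal scaling (-0.44). Of 22 endocrine islet genes, 18 fell (19 adjusted over the list alone) and 1 rose (median -1.57), against 9 and 2 with a median of -0.88 under the ribosomal scaling. G6pc2 of beta cells fell by 2.96 ± 0.39, Ttr by 2.87 ± 0.48 and the granule protein gene Chga by 2.58 ± 0.40. Ppy, the pancreatic polypeptide gene, rose by 1.31 ± 0.44 (adjusted p = 0.0353), a call lost without control replicates 1 (1.14) or 2 (1.22), without PDAC replicates 1 (0.93) or 2 (1.19), without variance shrinkage, with a variance trend, with the second quantile normalization and with the replicate block. The camera adjusted p was 6.09e-10, 1.13e-05 and 0.000177 for the 3 lists, and 0.241, 0.241 and 0.403 with an estimated correlation.

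Stromal genes rose. All 32 measured genes of the extracellular matrix list were higher, with a median of 2.22. Beside Tnc, Timp1 and Col12a1, the proteoglycan gene Vcan rose by 4.41 ± 0.25 and the collagen gene Col1a1 by 3.05 ± 0.15. Of 19 fibroblast and stellate cell genes, 17 rose and 2 fell (median 1.98). Postn rose by 3.81 ± 0.33, Thy1 by 3.07 ± 0.19 and Acta2, the smooth muscle actin of activated stellate cells, by 2.3 ± 0.2. Gsn fell by 0.97 ± 0.14 and Dpt by 0.75 ± 0.27. Both of these calls were lost under the ribosomal scaling (-0.28 and -0.06), and that of Dpt also without control replicates 1 (-0.86), 2 (-0.58) or 3 (-0.81), without PDAC replicates 1 (-0.66) or 3 (-0.55), with a variance trend, with array weights, with age and without variance shrinkage. Of 21 genes of epithelial-mesenchymal transition and TGF-beta, 19 rose and 0 fell (median 1.95), among them the activin gene Inhba (4.08 ± 0.20), Ccn2 (3.58 ± 0.23), Pmepa1 (3.48 ± 0.10) and Zeb1 (1.5 ± 0.2). Of 18 endothelial genes, 7 rose and 0 fell (median 0.41), with Eng at 1.03 ± 0.20 and the tight junction gene Cldn5 at 0.87 ± 0.10. Pecam1 changed by 0.05 (adjusted p = 0.823). Under the ribosomal scaling 16 rose, Pecam1 (0.74) among them, and under the second quantile and median scalings 4 rose and 1 fell in each. The camera adjusted p was 3.46e-16, 2.90e-06, 1.27e-09 and 0.027, in that order, and 0.241, 0.264, 0.241 and 0.627 with an estimated correlation. The endothelial list's camera call was also lost without PDAC replicate 1 (median 0.19) or control replicate 3 (median 0.39), with the dim filter (0.41), with the ribosomal scaling (1.10) and with the second quantile normalization (0.24).

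Myeloid genes rose, while the T and NK and the B and plasma cell lists did not pass. Of 22 macrophage and monocyte genes, 21 rose (22 adjusted over the list alone) and 0 fell (median 2.85), with the arginase gene Arg1 at 4.36 ± 0.25, the cathepsin gene Ctss at 4.14 ± 0.22 and Cd68 at 2.67 ± 0.20. Of 16 neutrophil genes, 11 rose and 1 fell (2 adjusted over the list alone; median 1.64). Mmp9 rose by 3.85 ± 0.45 and the chemokine receptor gene Cxcr2 by 2.24 ± 0.20. S100a8 rose by 1.18, a call lost without control replicate 2 (1.09) and without variance shrinkage. Camp fell by 0.30, a call that all but 1 of the fits without an array lost (-0.30 without control replicate 1, -0.29 without 2, -0.30 without 3, -0.30 and -0.26 without PDAC replicates 1 and 3), as did the replicate block, and that turned to 0.39 under the ribosomal scaling. Of 10 genes of MHC class II presentation, 8 rose (median 1.90), with Cd80 at 2.98 ± 0.17 and H2-Aa at 2.20 ± 0.24. Of 27 cytokine and chemokine genes, 24 rose and 0 fell (median 1.5), with the interleukin-1 antagonist gene Il1rn at 4.19 ± 0.29, the cyclooxygenase gene Ptgs2 at 3.69 ± 0.16 and Il6 at 2.46 ± 0.11. Of 19 interferon response genes, 11 rose (median 0.72; 18 under the ribosomal scaling), with Oasl2 at 1.25 ± 0.18 and Ifit1 at 1.16, the latter call lost without control replicates 1 (1.19), 2 (1.15) or 3 (1.14) and without variance shrinkage. The camera adjusted p of these 5 lists was 4.46e-11, 0.000508, 0.000194, 1.21e-08 and 0.00119, in that order, and 0.297, 0.297, 0.324, 0.246 and 0.481 with an estimated correlation. The neutrophil and interferon calls were also lost with the dim filter, where their medians were 1.89 and 0.87.

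Of 18 T and NK cell genes, 0 rose and 3 fell (1 adjusted over the list alone), namely Cd8b1 (-0.62 ± 0.10), Cd8a (-0.45) and Cd247 (-0.38), and under the ribosomal scaling all 3 stood above 0 without passing. The calls of Cd8a and Cd247 were also lost in some fits without an array (Cd8a at -0.34 without control replicate 3, -0.36 without PDAC replicate 1 and -0.46 without PDAC replicate 3, as well as without variance shrinkage; Cd247 at -0.36 without control replicate 1 and -0.34 without PDAC replicate 3). Under that scaling 12 of the 18 rose and 0 fell (median 0.54), among them Cd3e (0.76), which changed by 0.07 under the deposited one (adjusted p = 0.76). The list's median was -0.15, which is -0.03 from that of all genes, and its camera adjusted p was 0.447. Cd8b1, Cd8a and Cd247 were dim in control pancreas. Their means of 6.67, 6.22 and 6.21 lay near or below the control array medians (6.65 to 6.74). Of 14 B and plasma cell genes, 4 rose and 4 fell (median 0.03, camera adjusted p = 0.993), against 8 and 0 with a median of 0.72 under the ribosomal scaling. The antibody joining chain gene Jchain rose by 3.43 ± 0.72 and the heavy chain gene Ighm by 2.41 ± 0.75, the latter call lost without control replicates 1 (2.20), 2 (2.54) or 3 (2.49), with a variance trend and without variance shrinkage. Fcmr fell by 0.69 ± 0.12 and the B cell factor gene Pax5 by 0.54 ± 0.10. Under the ribosomal scaling they stood at -0.003 and 0.15, neither past the threshold. Their control means of 6.57 and 6.43 also lay below the control array medians.

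Intestinal and adipocyte markers stood high in 1 array each. Of 15 intestinal epithelium genes, 3 rose, the cadherin gene Cdh17 (5.11 ± 0.24), Lgals4 (3.97 ± 0.40) and Vil1 (2.38 ± 0.14), and Cdx1 fell by 0.97, a call lost under the ribosomal scaling (-0.28). The list's median was 1.03 (camera adjusted p = 0.0816), but it was 3.20 in PDAC replicate 2 against -0.28 and 0.03 in PDAC replicates 1 and 3, and without that array the median change was -0.15. The list passed in the fits without PDAC replicates 1 (median 1.82) or 3 (1.52), with the second quantile normalization, with array weights and with median scaling, all of which keep PDAC replicate 2. Under the ribosomal scaling 5 of its genes rose and 0 fell. Of 12 adipocyte genes, 0 rose and 4 fell (1 adjusted over the list alone; median -0.98, camera adjusted p = 0.0734), with Plin1 of the lipid droplet at -1.0 ± 0.2 and -0.31 under the ribosomal scaling, which ended its call. The adipocyte list passed without control replicate 1 (median -1.06), without PDAC replicate 1 (-0.98), with the replicate block and with the ribosomal scaling, where 2 genes rose and 0 fell, and under the second quantile and median scalings 7 and 9 fell. Control replicate 2 had the highest of the 3 control values for most adipocyte genes, with Adipoq at 8.14 there against 5.85 and 6.12 in the other controls. Of 13 nerve and glia genes, 2 rose and 5 fell (median -0.05, camera adjusted p = 0.993), against 7 and 0 with a median of 0.64 under the ribosomal scaling. The adhesion molecule gene Ncam1 rose by 3.05 ± 0.23 and Uchl1 by 0.65, while the myelin gene Mbp fell by 0.80 and Gfra3 by 0.77, both without a call under the ribosomal scaling (-0.11 and -0.08). Of 3 measured erythroid genes, 1 fell, Slc4a1 (-0.56). That call was lost without control replicate 1 (-0.51) and without variance shrinkage, and the change turned to 0.13 under the ribosomal scaling.

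**Figure D3:**
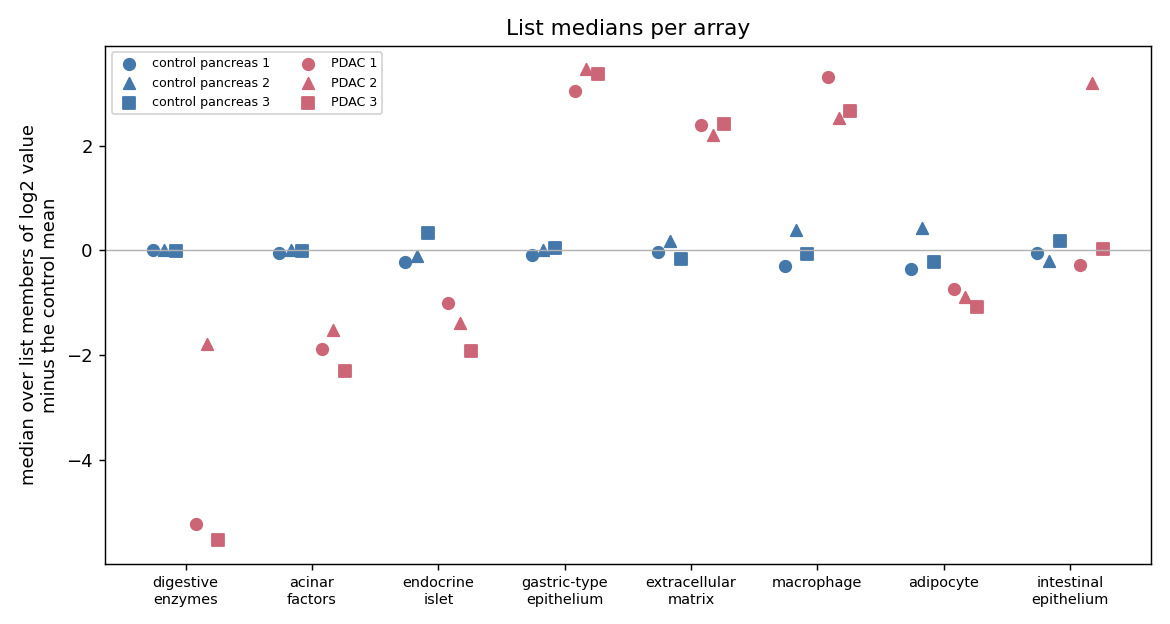
Median over the members of 8 gene lists of each array's log2 value minus the control mean (vertical axis), with control pancreas in blue, PDAC in red and the replicate number as marker shape. PDAC replicate 2 (triangles) lies at -1.79 for digestive enzymes and 3.20 for intestinal epithelium, apart from the other tumours at -5.23 and -5.54 and at -0.28 and 0.03.

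Proliferation and growth factor signalling genes rose. Of 35 cell cycle genes, 32 rose (33 adjusted over the list alone) and 0 fell (median 1.43), with the mitotic checkpoint kinase gene Bub1 at 3.07 ± 0.21, Ccna2 at 2.89 ± 0.30 and Mki67 at 2.25 ± 0.31. Of 23 genes of RAS and ERK output, 21 rose and 1 fell (median 2.12). Il1a rose by 4.23 ± 0.16, the ERK phosphatase genes Dusp4 and Dusp6 by 3.79 ± 0.23 and 3.22 ± 0.25, and the receptor kinase gene Epha2 by 3.07 ± 0.22. Myc fell by 0.50 ± 0.15, a call lost without control replicate 2 (-0.34), without PDAC replicate 1 (-0.43) and without variance shrinkage, and a sign that turned under the ribosomal scaling (0.19). The camera adjusted p was 4.11e-13 and 1.11e-09 for the 2 lists, and 0.246 for both with an estimated correlation. Of 17 p53 target genes, 5 rose and 6 fell (median 0.16, camera adjusted p = 0.455), against 11 and 1 with a median of 0.85 under the ribosomal scaling. The death receptor gene Tnfrsf10b rose by 2.52 ± 0.18, Phlda3 by 2.39 ± 0.20 and, named after their values were seen, Eda2r by 1.33 and Mdm2 by 0.91. Plk2 fell by 1.55 ± 0.17, Sesn1 by 0.98, Bbc3 by 0.86 and Perp by 0.72. Only 1 gene of the list was lower under the ribosomal scaling, so most of these falls lost their call there. Of 14 genes of pancreatic injury and the acute phase, 5 rose and 4 fell (camera adjusted p = 0.474). The median was -0.30, the mean 0.02 and the direction of the test upward; under the ribosomal scaling 6 rose and 2 fell (median 0.39). PDAC replicate 2 stood apart, with a list median of 0.66 against the control means where PDAC replicates 1 and 3 had -0.45 and -0.79. Saa3 rose by 4.40 ± 0.46 and Cp by 2.12. Reg3d fell by 4.76 ± 1.17, a call lost without variance shrinkage, and the stress response gene Nupr1 fell by 2.77 ± 0.18. Reg1 fell by 1.40 ± 0.43, a call lost without control replicates 1 (-1.39), 2 (-1.40) or 3 (-1.41), with a variance trend, without variance shrinkage and under the ribosomal (-0.71) and second quantile scalings.

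The study these arrays come from concerns metabolism in PDAC, with interest in lipids and cholesterol. The arrays measured whole tissue in which macrophage and fibroblast genes rose and acinar genes fell. The metabolic changes below therefore cannot be assigned to tumour cells. Of 19 cholesterol synthesis genes, 10 rose and 1 fell (median 0.56, camera adjusted p = 0.0166, and adjusted p = 0.639 with an estimated correlation). The median lay inside the central 95% of random lists matched on mean expression (-0.26 to 0.62), and under the ribosomal scaling 18 rose and 1 fell. Hsd17b7 rose by 1.56 ± 0.21, Msmo1 by 1.51 ± 0.16 and Hmgcs1, which makes the substrate of the rate-limiting reductase, by 1.19 ± 0.26. The call of Hmgcs1 was lost without variance shrinkage. Insig1, which restrains the pathway, fell by 1.67 ± 0.25. The list's camera call was also lost without PDAC replicate 1 (median 0.41), with the dim filter (0.59) and with the ribosomal scaling (1.25). Of 22 genes of lipoprotein and cholesterol handling, 10 rose and 6 fell (median 0.45, camera adjusted p = 0.0553), against 15 and 2 under the ribosomal scaling. The lipoprotein receptor gene Lrp1 rose by 2.66 ± 0.21 and the apolipoprotein gene Apoe by 1.84 ± 0.22, while the fatty acid receptor gene Cd36 fell by 2.26 ± 0.51, a call lost without variance shrinkage, and the receptor gene Vldlr fell by 1.90 ± 0.20. This list passed in the fits without control replicate 2 (median 0.55) and without PDAC replicate 3 (median 0.57) and with median scaling. Of 20 fatty acid synthesis genes, 6 rose and 7 fell (median 0.10, mean -0.08, camera adjusted p = 0.898; 11 and 3 under the ribosomal scaling), with Me1, the malic enzyme that makes NADPH, at 2.92 ± 0.19 and the carboxylase gene Acacb at -2.91 ± 0.18. The other carboxylase gene, Acaca, rose by 0.77 ± 0.18, a call lost without variance shrinkage. Of 19 fatty acid oxidation genes, 11 fell and 2 rose, with a median of -0.52 that turned to 0.17, with 4 lower and 9 higher, under the ribosomal scaling and lies -0.40 from that of all genes (camera adjusted p = 0.0149, and adjusted p = 0.471 with an estimated correlation). Under the ribosomal scaling the list still passed camera (adjusted p = 0.00254), and its median lay below that of all genes there (0.57). The peroxisomal enzyme gene Ehhadh fell by 2.42 ± 0.17 and the receptor gene Ppara by 1.77 ± 0.11, and Slc25a20 and Acadl rose by 0.72 and 0.53. Cpt1a, of the carnitine shuttle, changed by -0.15 (adjusted p = 0.495), and rose under the ribosomal scaling (0.54).

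Among 25 genes of glycolysis and hypoxia, 18 rose (19 adjusted over the list alone) and 4 fell (median 1.25, camera adjusted p = 4.12e-05, and adjusted p = 0.349 with an estimated correlation). The oxygen sensor gene Egln3 rose by 3.24 ± 0.38, the glucose transporter gene Slc2a1 by 2.59 ± 0.15 and Car9 by 2.54 ± 0.22, while Ndrg1 fell by 1.51 ± 0.13 and the kinase gene Pdk1 by 1.03 ± 0.11, a call lost under the ribosomal scaling (-0.34). Of 9 genes of hexosamine synthesis and O-GlcNAc, 5 rose and 1 fell (median 0.47, camera adjusted p = 0.0485, and adjusted p = 0.264 with an estimated correlation). Of the 2 genes for the rate-limiting enzyme, Gfpt2 rose by 1.80 ± 0.20 while Gfpt1 changed by -0.31 (adjusted p = 0.117), a fall that passed without PDAC replicate 2 (-0.44) and with median scaling (-0.49) and a sign that turned under the ribosomal scaling (0.38). Among the others, Gnpda2 rose by 1.19, Oga by 1.10 ± 0.13 and Ogt by 0.75. Gnpnat1 fell by 0.49, a call lost without control replicates 1 (-0.44) or 3 (-0.38), without PDAC replicates 1 (-0.46) or 3 (-0.48), with the replicate block and without variance shrinkage, and a sign that turned under the ribosomal scaling (0.20). The list's camera call was lost without PDAC replicates 1 (median 0.44), 2 (0.54) or 3 (0.44), with the replicate block, with age and with the dim filter (0.47 in each) and with the ribosomal (1.16) and second quantile (0.25) scalings.

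Of 27 oxidative phosphorylation genes, 19 fell and 0 rose, with a median of -0.57 that turned to 0.12, with 10 higher and 4 lower, under the ribosomal scaling and lies -0.45 from that of all genes (camera adjusted p = 8.25e-05, and adjusted p = 0.324 with an estimated correlation). Under the ribosomal scaling the list still passed camera (adjusted p = 0.000111), and its median lay below that of all genes there (0.57). Ndufa1 of complex I fell by 1.45 ± 0.15 and Sdhb of complex II by 1.34 ± 0.09. Of 25 cytosolic ribosomal protein genes, 20 fell and 1 rose, with a median of -0.45 that turned to 0.24, with 2 lower and 7 higher, under their own scaling and lies -0.32 from that of all genes (camera adjusted p = 0.000177, and adjusted p = 0.248 with an estimated correlation). That scaling holds the list's own median equal between arrays, so the turn is built in and says nothing about these genes. Rpl13 fell by 1.19 ± 0.12 and Rpl5 by 1.07 ± 0.11, although another probe set of Rpl13 rose by 2.62. Rpl27 rose by 0.32, a call lost without control replicates 1 (0.31) or 2 (0.31), without PDAC replicates 1 (0.28) or 2 (0.30), with the replicate block and with median scaling, and the mean of its probe sets was -0.18. Of 23 lysosome and autophagy genes, 8 rose and 6 fell (median 0.19, camera adjusted p = 0.272), against 18 and 0 with a median of 0.88 under the ribosomal scaling. Lamp1 changed by -0.10 (adjusted p = 0.509) and rose under that scaling (0.59). The members with the largest rises were the lysosomal protease genes Ctsz (1.37 ± 0.12) and Ctsl (1.29 ± 0.13). Those that fell included the autophagy kinase gene Ulk1 (-0.66) and, named after their values were seen, the autophagosome genes Map1lc3b (-0.53) and Gabarapl2 (-0.51), all 3 without a call and above 0 under the ribosomal scaling.

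In all, 24 of 34 lists passed camera at the preset correlation, 16 upward and 8 downward, and 0 passed with an estimated correlation (smallest adjusted p 0.241; 6 had an unadjusted p under 0.05, the smallest 0.0167). That setting also takes its degrees of freedom from the 6 arrays rather than the many genes, so correlation alone need not explain the loss. The hexosamine list had an estimated correlation of -0.034, below the preset 0.01, yet its unadjusted camera p rose from 0.0342 to 0.0926. Fry, which tests whether the genes of a list move on balance in 1 direction, passed 23 lists. Its test for change in either direction passed 34. The other 9 splits of the 6 arrays into 3 and 3 passed between 16 and 27 lists with camera at the preset correlation. Each of them mixes both groups on both sides and keeps part of the group difference, so these counts do not measure calls by chance. The list calls are to be read with the gene counts beside them. Where no second count is given above, adjustment over the list alone gave the same count.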

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

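The lists of intestinal, gastric gland and smooth muscle genes tested here were chosen after the patterns they bear on were seen, though before their own values were. The comparison with matched random lists was likewise chosen after the main result. The reading of 2 of these tests was also made stricter after their values were seen: the second intestinal list must have a majority of genes above the bound, as its prediction said, and a list must lie beyond its matched lists by more than its own bootstrap interval. Read by the medians alone, as at first, the values would have favoured intestinal mucosa and spoken against scaling as the cause of the ribosomal change. Single genes of these lists and of the intestinal list are named below after their values were seen. Groups of 3 arrays were not tested for single outlying arrays.

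Of the 11799 probe sets that the annotation table does not name, 2887 were higher and 2987 lower in PDAC, and 1683 and 551 of them by at least 2-fold. The largest change in each direction was 5.19 and -6.29. Of the 1321 probe sets with several gene symbols, 238 were higher and 449 lower, with changes between -4.08 and 5.44. These probe sets carry signal that the comparison of genes does not use.

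PDAC replicate 2 differed from the other tumours in intestinal and acinar genes. On that array Muc2 stood at 11.81, Alpi at 11.10, Apoa1 at 10.66 and Apoa4 at 10.18, against 5.92 to 8.04 in PDAC replicates 1 and 3, and 358 genes lay more than 1 log2 above the mean of the other tumours where 46 lay more than 1 below. A piece of intestinal mucosa in the sample would raise other abundant intestinal genes: a second list of 20 such genes had a median excess of 1.09 there, with Lypd8 at 12.65 against 6.64 and 8.02, but 10 of the 20 lay above 1, which falls short of the majority required beforehand, and Ang4 and Olfm4 had excesses of 0.11 and 0.46. Smooth muscle genes of the gut wall had a median excess of -0.09, under the bound of 0.5 set beforehand, which argues against a piece of gut wall with its muscle: 7 of the 11 genes were higher in PDAC than in control pancreas, but the 4 that were not (Synpo2, Synm, Hand1 and Pgm5) had excesses between -0.05 and 0.29 too. So intestinal mucosa and tumour cells that express intestinal genes cannot be told apart here. Of the acinar genes, 26 of 27 digestive enzyme genes lay more than 1 above the other tumours. Normal pancreas left in that sample is an untested explanation for the acinar genes only.

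Gastric-type genes (Ctse, Gkn2, Muc5ac) rose in each of the 3 tumours. Adjacent stomach taken with the tumours would bring its gland genes too, and a list of 11 of these had a median change of -0.19 with an upper quartile of 0.05, Atp4b of the acid pump falling by 0.80 and Pga5 by 1.16. That argues against stomach wall with its glands as the source in the group, less firmly under the ribosomal scaling. The median was 0.50 there with 6 of 11 genes higher, but that scaling shifts every gene alike. Set against the median of all genes, the list lay at -0.07 under both scalings. Slc26a9 alone of the list rose (3.93), and in PDAC replicate 2 the gland genes Pgc and Cblif lay 2.51 and 1.19 above the other tumours, so a share of gastric tissue in that sample stays open, as does surface mucosa without glands in any of them. A biological explanation, gastric-type genes switched on in tumour epithelium, was not tested and remains a hypothesis.

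Genes of oxidative phosphorylation and of cytosolic ribosomes were lower in PDAC under the deposited scaling. The oxidative phosphorylation median was above 0 under the ribosomal scaling, but below the median of all genes there (0.57). That scaling holds the ribosomal protein list's own median equal between arrays, so the list's 0.24 there is built in and no result. A wrong scaling would lower other genes of the same brightness as far. The oxidative phosphorylation list's median was -0.57, with a bootstrap interval over its genes of -0.73 to -0.30. The 2.5th percentile of 10000 random lists matched on mean expression was -0.28, so the list lay below genes of its brightness. Both intervals draw genes independently, while the list's estimated correlation between genes was 0.235, so they are likely too narrow. The values speak against scaling alone as the cause but do not exclude it. The ribosomal protein list's median of -0.45 lay past the matched bound of -0.43, but its own interval of -0.71 to -0.33 covers that bound, so scaling may account for it and the test leaves the question open. A uniform scaling error would still move the absolute sign of both, and a lower share of acinar cells, whose RNA makes up most of normal pancreas, is a biological explanation that was not tested.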

How the results depend on the processing

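Scaling to a common median was chosen after seeing the data, and the other alternatives beforehand. The planned filter on probe set suffixes was not run, since the probe identifiers carry none, and without variance shrinkage no set test was made. Of the recomputed values, 113 counts stayed within 1.5 times the main count and 7 moved further. The total of called genes entered these counts more than once per setting. In all, 458 list medians and 2427 changes of single named genes kept their direction and their side of the threshold. Of the other list medians, 21 turned, 18 lost their call and 12 gained a call. Of the other gene changes, 35 turned, 94 lost their call and 7 gained a call. Signal over background limits the dim genes: without the dimmer probe sets the split was 4715 higher and 3209 lower (59.5% higher, against 45.87%), a test of fewer genes, and the nerve list's median turned to 0.326. The ribosomal scaling raised the median change of all genes from -0.122 to 0.567, by construction a shift of every gene. It also holds the ribosomal protein list's own median equal between arrays, so that list's turn is built in. It gave 13117 higher and 994 lower genes (92.96% higher), 5838 and 424 by at least 2-fold, and called 775 genes in the opposite direction. Medians turned under it for the T and NK (0.538), nerve (0.638), injury (0.388), fatty acid oxidation (0.166), oxidative phosphorylation (0.115) and ribosomal protein (0.245) lists, and changes for Camp (0.39), Cd247 (0.308), Cd8a (0.236), Cd8b1 (0.066), Cdkn2a (0.681), Cpt1a (0.542), Dnase1 (0.456), Gabarapl2 (0.185), Gfpt1 (0.378), Gnpnat1 (0.197), Hspa5 (0.278), Lamp1 (0.591), Map1lc3b (0.165), Myc (0.189), Pax5 (0.146), Pdx1 (0.232), Slc4a1 (0.129), Ulk1 (0.026) and Xist (0.419). Median scaling took the median change of all genes to -0.303, gave 4301 higher and 9483 lower genes (31.2% higher) and turned the B cell (-0.155), p53 target (-0.018) and fatty acid synthesis (-0.081) medians, Cd3e (-0.111) and Pecam1 (-0.13). The second quantile normalization gave 4501 and 6965 genes (39.26% higher) and turned the B cell (-0.023) and fatty acid synthesis (-0.061) medians, Cd3e (-0.077) and Pecam1 (-0.157). Array weights turned Pecam1 (-0.022). With the mean of a gene's probe sets, the lysosome median was -0.004 and Rpl27 -0.175. For these sign changes the cause was not tested. At an adjusted p under 0.01, a stricter threshold, 3735 genes were lower. Without variance shrinkage Pdx1 (-0.458) no longer passed. With an estimated correlation camera passed 0 lists (6 at an unadjusted p under 0.05), and fry 23.

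Leaving out 1 array at a time gave 9808 to 10753 genes past the threshold, 4696 to 5207 higher and 5014 to 5862 lower, 2247 to 2481 and 1125 to 1200 by at least 2-fold, and 23 to 25 lists. Without PDAC replicate 2, the array that stood apart, 5207 were higher and 5373 lower. Over these fits the change of Cdkn2a ran from -0.082 to 0.058, that of Pdx1 from -0.583 to -0.349, Cd3e from -0.093 to 0.231, Cpt1a from -0.281 to 0.03, Lamp1 from -0.192 to 0.003, Pecam1 from -0.135 to 0.208, and the list medians from -0.162 to 0.278 for B cells, -0.296 to 0.102 for nerve, -0.151 to 1.818 for intestinal epithelium and -0.768 to 0.099 for the injury list. Nothing in the labels says that the replicate numbers pair the arrays. Deviations from the group means correlated by -0.044, -0.076 and 0.066 between arrays of the same number. Not every array correlated best with its own number. With so few arrays these values cannot exclude a pairing. With the replicate block 5154 genes were higher, 5743 lower and 24 lists passed.

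Only 1 of the 10 splits of the 6 arrays, the real one, gave as many genes: 11789 in all, 5408 higher, 6381 lower, and 2348 and 1177 by at least 2-fold, where the highest of the others was 0 for each. For lists 3 of the 10 splits gave as many as the real 24, and the highest other gave 27. With 10 splits the share cannot fall under 0.05. Every other split mixes both groups on both sides. It keeps part of the group difference and carries the rest as spread within each side. Few genes and many lists can then pass whatever the cause, so neither count measures chance. The mixed splits, with 0 genes, passed 16 to 27 lists with camera at the preset correlation.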

Other observations

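The tests of gene families, olfactory receptors and the mast cell list below were chosen after the main result was seen, and the single genes outside the report's naming rule were named after their values were seen. Families defined by the letters of the gene symbol were tested with camera at the preset correlation, and 35 of 309 passed, 20 upward and 15 downward, while 0 passed with an estimated correlation (smallest adjusted p 0.685, 16 at an unadjusted p under 0.05). The smallest camera adjusted p belonged to olfactory receptors (Olfr, 3.52e-06, median -0.28) and Vmn receptors (0.000138, median -0.31). Both medians turned under the ribosomal scaling, to 0.41 and 0.38. The Defb, Krtap, Tex and Taar families also passed downward and turned there. Among annexins, which bind membranes in the presence of calcium, 11 of 12 genes rose and 0 fell (median 1.21). Under the ribosomal, second quantile and median scalings 12, 9 and 9 rose. Of 10 toll-like receptor genes 9 rose (median 1.77), of 9 caspase genes 8 (median 1.25), of 12 integrin alpha genes 8 (median 0.83) and of 20 semaphorin genes 11 (median 0.82), and these medians stayed above 0 under all 3 other scalings. Of 8 immunoglobulin kappa variable genes, whose probe sets can cross-hybridise, 7 rose (median 2.07, adjusted p = 0.0471, and between 1.89 and 2.76 under the other scalings), while the list of B and plasma cell genes did not pass. Of 20 nucleoporin genes, which form the nuclear pore, 15 rose and 3 fell (median 0.78, and between 0.60 and 1.47 under the other scalings). Of 10 Dock genes, activators of small GTPases, 9 rose (median 1.32), again above 0 under the others (1.13 to 2.01).

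Of 29 mitochondrial ribosomal proteins of the small subunit, 17 fell and 1 rose (median -0.44), but the median was 0.25 with 12 higher under the ribosomal scaling. Of 9 Ndufb genes of complex I, 7 fell (median -0.91), and the median kept its sign under the others (-1.12 to -0.22). Under the ribosomal scaling 3 fell and 2 rose. Of 14 peroxin genes, which build peroxisomes, 10 fell and 1 rose (median -0.49), turning to 0.20 under the ribosomal scaling.

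The 1027 olfactory receptor genes, which belong to nasal sensory neurons, had a median value of 4.45 in control pancreas and 4.18 in PDAC, and 400 were lower against 4 higher (median -0.28), 5 of them at least 2-fold lower. Under the ribosomal scaling the median was 0.41, with 602 higher and 3 lower. Small changes of dim genes in either direction thus lie within what the choice of scaling moves.

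Mcpt2 and Mcpt1, chymases of mucosal mast cells, were among the 12 genes with the largest rises, and (named after their values were seen) Mcpt8, a basophil protease gene, rose by 4.57 and Mcpt4 by 1.65. A hypothesis was that the tumours hold more mast cells, which would raise their other genes too. A list of 13 mast cell and basophil genes, 1 of them Mcpt4, had a median change of 0.18 and an upper quartile of 0.33. Of these 3 rose, Mcpt4, Tpsab1 (1.23) and Fcer1a (0.44), while Kit, which other cells also express, fell by 1.16, and the abundant mast cell gene Cpa3 changed by 0.18 (adjusted p = 0.547). Under the second quantile and median scalings the median was 0.10 and 0.00. Under the ribosomal scaling, which shifts every gene alike, it was 0.87 with 11 of 13 genes higher. Set against the median of all genes, it lay at 0.30 under both the deposited and the ribosomal scaling. Under the deposited scaling the list's median thus does not show a general rise of mast cell genes. Several members (Mrgprb2, Ms4a2 and Fcer1a) lay near background on all arrays, and the list was not chosen for the mucosal kind. It therefore cannot exclude more mucosal mast cells. A smaller increase stays open too. Cross-hybridisation between the protease genes, basophils, a change in the kind of mast cell or expression in other cells remain untested.

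Against random lists matched on mean expression, a test chosen after the main result, the glycolysis and hypoxia median of 1.25 lay above the central 95% (-0.28 to 0.52), the fatty acid oxidation median of -0.52 below it (-0.30 to 0.62), though with a bootstrap interval of -1.02 to -0.10 that covers the bound, and the cholesterol synthesis (0.56) and lysosome (0.19) medians inside it.

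Control replicate 2 held the highest values of several adipocyte genes. Car3 stood at 11.68 there against 8.02 and 8.99 in the other controls, and Cidec at 8.86 against 7.03 and 7.33 (both named after their values were seen). Without that array Adipoq passed the threshold, at -0.44.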
